A study of Mus musculus with 6 samples.

How the data were processed

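Total RNA of mouse bone-marrow-derived macrophages, labelled as polarized M2 cells, was amplified and labelled with Cy3 and hybridised to 1-colour Agilent arrays, per the labels' protocols. There were 3 deposited files of cells kept 6 h in medium and 3 of cells kept 6 h in medium with WGP, and groups and replicate numbers were taken from the labels. The arrays were scanned and read out with Agilent Feature Extraction 10.7.3, per the submitters' processing notes. The values used are intensities per spot, and per the file headers the processed signal is the spot's intensity after background subtraction and spatial detrending, with no normalization between arrays. The flags for being well above background, saturated or an outlier were also deposited by the authors. A table of log2 values deposited by the authors for the whole series was compared with the scanner files. After centring each probe, its values correlated at 1 with log2 of the processed signal minus the array's 75th percentile over 39394 probes, with a largest difference of 0.0107. Its columns had medians of -0.0145, 0.164 and 0.103 for medium replicates 1 to 3 and of 0.0997, 0.130 and 0.100 for WGP replicates 1 to 3. The baseline to which each probe was centred stays unknown, and the table was used as an alternative only.

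Before averaging, the files of each group were compared spot by spot over 44397 spots. Replicates 1 and 2 differed in median signal at 43490 spots in medium and 42356 spots with WGP. Replicate 3 differed from replicate 1 in median signal, background, flag and position at 0 spots in both groups. The processed signal of medium replicate 3 lay within 1% of the mean of medium replicates 1 and 2 at all 44397 spots, and that of WGP replicate 3 within 1% of 1.3 times WGP replicate 1 at all 44397 spots. The design fixed before the data were examined was to average files that hold the same values. WGP replicate 3 was averaged with WGP replicate 1. Medium replicate 3 was left out, a departure from that design, because averaging it with replicate 1 would mix replicate 2 into replicate 1. Averaging it as written was added as an alternative after seeing the data. Every group thus had n = 2 independent arrays.

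Per the file headers, replicate numbers 1 and 2 were also a slide and a scan each, with medium at position 1 and WGP at position 3 of both slides. The header of medium replicate 3 named a slide of its own but the scan of replicate 1, and that of WGP replicate 3 named the slide, position and scan of WGP replicate 1. The pairing by slide comes from these headers, not from the labels. The deviations of the arrays from their group means correlated at 0.14 between the arrays of a slide, over 2 pairs. The fit with the slide as a block was an alternative and is given beside the count of changed genes.

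Control spots (1377) and spots flagged as outliers (118 to 183 per array) were left out, and 0 spots were saturated. Log2 of the processed signal minus the array's 75th percentile was averaged over the spots of a probe. Of 39429 probes, 26761 (67.87%) were named through their accession in a RefSeq gene table of assembly GRCm38.p6, giving 20283 genes. The array design is on an older build, so no coordinates are given. Probes with superseded accessions stayed unnamed, among them those meant for some well-known macrophage genes, which were not analysed here. A probe was kept if it was well above background on both arrays of at least 1 group, where a probe with several spots needed a share of at least 0.5 of them well above background, and 16 probes with missing values were dropped. Of the 18442 probes kept, the brightest named probe stood for each of 10947 genes. In 95 of 1150 changed genes with several kept probes, another probe had the opposite sign.

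Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, with 2 residual and 2.19 prior degrees of freedom) and Benjamini-Hochberg adjustment, with a threshold of 0.05. Every adjusted p given for a gene comes from limma. On the 4 arrays, the SD over genes of the difference between replicates was 0.39 in medium and 0.37 with WGP, against 0.87 for the difference between groups. The test was tried on simulated arrays drawn from the medium means of the 10947 genes, with their fitted spreads shuffled over genes and 200 changed genes. It recovered 0% of 67 changes of 0.5 on the log2 scale, 56.7% of 67 changes of 1 and 95.5% of 66 changes of 2, with 6 unchanged genes among 107 calls. The Benjamini-Hochberg cutoff depends on the share of changed genes. In the data 40.57% of genes were called, with absolute changes down to 0.334, so these recovery rates do not carry over to the real comparison.

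The 31 gene lists, from textbook knowledge, were fixed before the data were examined, with the test, the alternatives and the rule for named genes. Lists with at least 5 measured members (30) were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera with an estimated correlation, fry and a comparison with 10000 random lists of matched level were alternatives. Of the 582 genes measured in the lists, 48 stood on more than 1 list. The rule for named genes took the 8 largest rises and 8 largest falls among changed genes measured on every array, up to 3 genes per direction with the largest bound, 12 genes whatever their result, and the 2 changed members with the largest absolute fitted change, not bound, of each list (4 for each of the 2 polarization lists). The 12 genes were Arg1, Mrc1, Retnla, Chil3, Il10, Nos2, Il12b, Tnf, Il6, Il1b, Cd86 and Clec7a. Clone and predicted gene names were left out of the first 2 parts.

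The other alternatives were quantile normalization, median scaling, normexp with an offset of 50 followed by quantile or 75th percentile scaling, no filter or a stricter filter on dim probes, the mean of a gene's probes or each probe by itself, the slide block, eBayes with trend and robust, array weights, every array as its own sample, thresholds of 0.01 and 0.1, and leaving out each replicate. Normexp was run on the median signal, because no mean signal was used here. Without both arrays of replicate 1 or of replicate 2, 1 array per group is left and no test can be made. The first added alternative is named above, and the second counted only changed genes with no other kept probe of opposite sign. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.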

Results

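Gene expression was measured in bone-marrow-derived macrophages of C57BL/6 mice, labelled as polarized to the M2 (alternatively activated) state, after 6 h in complete medium alone or in complete medium with WGP. WGP, whole glucan particles, are particles of yeast cell wall that consist mostly of beta-glucan, a polysaccharide that macrophages recognize through C-type lectin receptors and take up. The labels do not say which agent polarized the cells. RNA was hybridised to Agilent 1-colour (Cy3) mouse arrays, and there were 3 deposited files for each group, medium and WGP. The files of replicate 3 held no hybridization of their own. Their spot signals and backgrounds before processing equalled those of replicate 1 of the same group at all 44397 spots. The processed signal of medium replicate 3 was the mean of medium replicates 1 and 2 to within 0.695% at every spot, and that of WGP replicate 3 was 1.3 times WGP replicate 1 to within 0.498%. WGP replicate 3 was therefore averaged with WGP replicate 1 and counted as 1 sample, and medium replicate 3 was left out, which leaves n = 2 independent arrays per group. The number of arrays limits the precision of every value below. The labels call the samples replicates but do not say that they came from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. On the 4 independent arrays, 50.6% and 46.5% of the 39429 probes were well above background in medium, and 46.6% and 45.0% with WGP. The 75th percentile of the processed signal, to which each array was scaled, was 85.8 and 68.6 in medium and 59.2 and 56.1 with WGP. All levels below are log2 of the processed signal minus that percentile, and all changes are WGP minus medium.

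The comparison asked which transcripts of these macrophages changed during 6 h with WGP. Acod1, the enzyme that makes itaconate from an intermediate of the citric acid cycle, showed the largest rise among genes measured on every array. Its level went from -0.96 ± 0.37 (SD, n = 2) in medium to 7.45 ± 0.057 with WGP, a 340.4-fold rise (8.41 ± 0.21 on the log2 scale, SE). Clec4e, which encodes the C-type lectin receptor Mincle, rose 134-fold (7.065 ± 0.19 on the log2 scale, SE), from 0.20 ± 0.32 to 7.26 ± 0.12. Next came the membrane glycoprotein podoplanin (Pdpn, 80.5-fold), the fatty acid receptor Gpr84 (78.4-fold), the protein C receptor Procr (53.8-fold), the dehydrogenase Bdh2 (34.0-fold), the collagen chain Col18a1 (26.8-fold) and the poly(A) polymerase Tent5c (22.5-fold). The largest fall among genes measured on every array was that of Clec10a, a galactose-binding C-type lectin of alternatively activated macrophages, from 3.80 ± 0.24 (SD, n = 2) to -0.23 ± 0.18, or 16.4-fold lower with WGP. Other large falls were those of the chemokine receptor Cxcr3 (14.1-fold lower), the orphan receptor Gprc5c (12.8-fold), the catenin Ctnnd2 (12.6-fold), the cytokine Il16 (11.8-fold), the transcription factor Zbtb16 (11.5-fold) and the organic anion transporter Slco2b1 (11.4-fold). The adjusted p of these genes lay between 0.00129 and 0.0016 in limma's test.

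Some genes were well above background on both arrays of one group and on neither array of the other, so that only a lower bound on the fold can be given. The bound sets the mean of the bright group against, per array of the dim group, the higher of the probe's own level and the lowest level of any probe well above background. With WGP, Cgref1 was at least 50.9-fold higher, the glutathione transferase gene Gsta3 at least 19.7-fold and Flrt3 at least 18.2-fold, each at an adjusted p of 0.00129 in limma. In the other direction, Mex3b was at least 14.6-fold lower (adjusted p = 0.00646), the lysophospholipid receptor gene Gpr34 at least 13.0-fold (adjusted p = 0.00234) and Fam214a at least 11.8-fold (adjusted p = 0.00129). The call of Mex3b was lost without medium replicate 2 (adjusted p = 0.058). In all, 131 genes that were higher with WGP were not well above background in medium, and 209 genes that were lower with WGP were not well above background with WGP. On each slide fewer probes were well above background on the WGP array (46.6% and 45.0%) than on the medium array (50.6% and 46.5%). These counts therefore do not show that more genes were lost than gained.

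**Figure D1:**
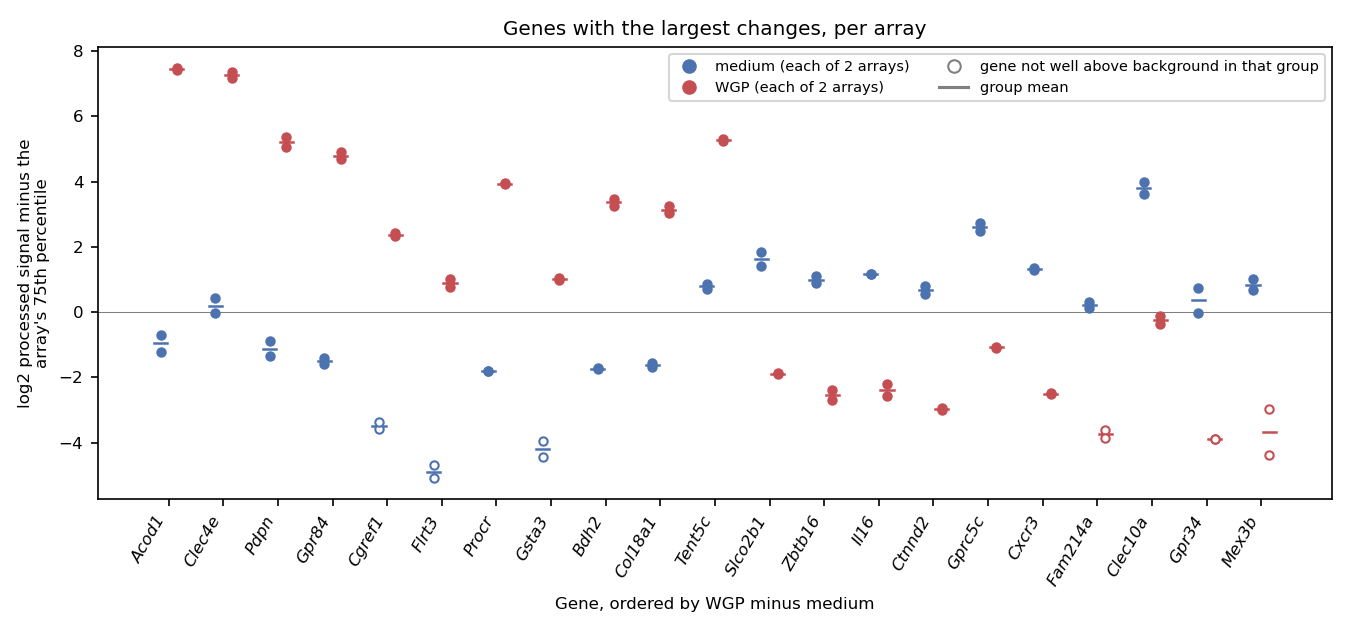
Levels of the genes named above with the largest measured changes or largest bounds (x axis) on each independent array, as log2 processed signal minus the array's 75th percentile (y axis). Points are arrays (2 of medium, 2 of WGP, WGP replicate 1 averaged with its scaled copy), lines are group means, and open points mark groups in which the gene was not well above background. Acod1 stands at a mean of -0.96 in medium and 7.45 with WGP, and Clec10a at 3.80 and -0.23.

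Of 10947 genes tested, 4441 (40.57%) changed at an adjusted p under 0.05, with 2539 higher and 1902 lower with WGP. Changes of at least 2-fold made up 1611 of these calls, 881 up and 730 down. The changed genes had a median absolute change of 0.80 on the log2 scale, with a median SE of 0.11. All 4441 had no overlap between the groups' arrays, which also fixes the same sign on both slides. With 2 against 2 arrays, 33.3% of genes would show no overlap by chance, and 75.07% of all tested genes did. Each slide carried 1 medium and 1 WGP array, at the same positions on both slides, so position on the slide went with treatment. The WGP minus medium differences of the 7 spiked-in control RNAs well above background on all arrays had an SD of 0.12, against 0.87 for the tested genes. Each of these controls was averaged over 32 spots, more than any gene's probe. With the slide as a block in the fit, 4090 genes changed, 2270 higher and 1820 lower. Within each slide there is 1 array per group and hence no test. Acod1 rose by 8.19 on slide 1 and 8.64 on slide 2, and Clec10a fell by 4.08 and 3.99, on the log2 scale. Across genes, which are not independent replicates, the changes on slide 1 and slide 2 correlated at 0.85. Without medium replicate 2, WGP replicate 1 or WGP replicate 2, the count of changed genes was 1884 (1008 higher, 876 lower), 2238 (1239 and 999) or 1715 (964 and 751), with the lone array of a group assumed to vary like the other group. With no filter on dim probes, 1532 of 20274 genes changed, and among named genes the calls of Mrc1, Il10, Il1b, Ndufa4, Atp6v1h, Mmp8, Cd79a, Col6a1 and Epor were lost (adjusted p of 0.0535 to 0.158). Background correction of the median signal by normexp left 561 or 559 changes of at least 2-fold, where its offset of 50 shrinks the changes of dim genes by construction. Scaling to the median in place of the 75th percentile moved the median change of all genes from 0.028 to 0.19, and the share of higher genes among those changed from 57.17% to 72.69%.

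**Figure D2:**
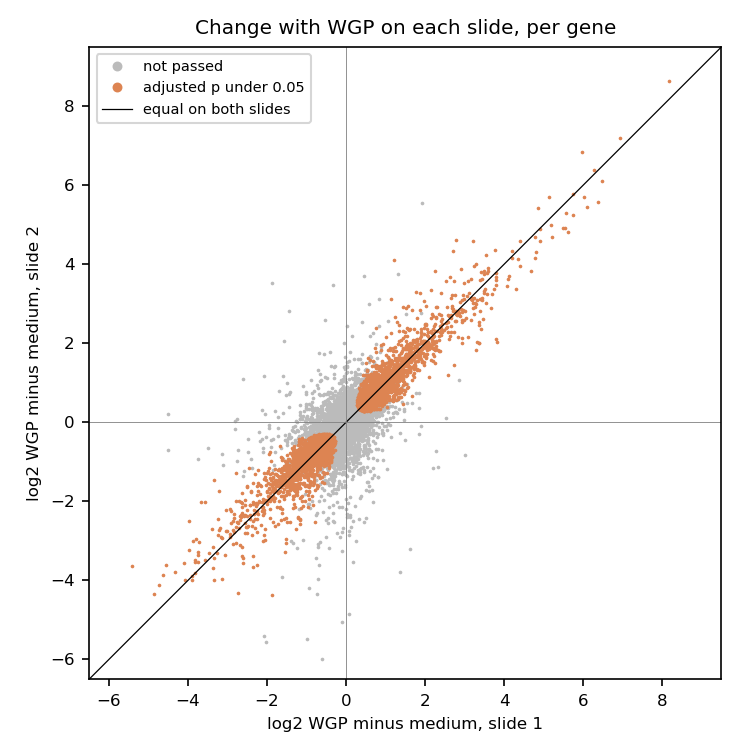
Change with WGP for each of the 10947 tested genes on slide 1 (x axis) and slide 2 (y axis), in log2 units, WGP minus medium, 1 array per group on each slide. Each point is a gene, coloured where its adjusted p over both slides was under 0.05, and the line marks equal changes. There are 4441 coloured genes, and the correlation over all genes is 0.85.

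Genes of classical (M1) activation rose as a group, while genes of alternative (M2) activation went both ways. Of 26 classical activation genes measured, 17 rose and 3 fell (the same numbers adjusted over the list alone), with a median change of 1.32. Besides Acod1, Tnf was at least 13.0-fold higher (adjusted p = 0.00129), the chemokine gene Ccl5 rose 7.96-fold (adjusted p = 0.00159) and the complement factor gene Cfb was at least 5.35-fold higher (adjusted p = 0.00383). The costimulatory molecule Cd86 rose 4.29-fold (adjusted p = 0.00262). Il1b rose 3.25-fold (adjusted p = 0.0253), with 1 of 2 medium arrays well above background, and its call was lost without WGP replicate 1 (adjusted p = 0.0876) or WGP replicate 2 (adjusted p = 0.0855). The 3 genes that fell were Il18, the Fc receptor Fcgr1 and the lipopolysaccharide receptor Tlr4. Nos2, the inducible nitric oxide synthase, did not pass the test (0.54 ± 0.58 on the log2 scale, SE, adjusted p = 0.496), and its medium arrays lay far apart (SD 1.07). Il6 was not well above background on any array, and 13 of the list's 39 genes with a named probe had no probe past the filter. The list passed limma's camera test (adjusted p = 0.0011), and its adjusted p = 0.4455 with an estimated correlation.

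Of 25 alternative activation genes measured, 8 rose and 7 fell (9 and 7 adjusted over the list alone), and the list did not pass camera (median 0.17, adjusted p = 0.636). Beside Clec10a, the scavenger receptor Cd163 fell to a level not well above background (at least 2.44-fold lower, adjusted p = 0.00156), a call that ended with normexp and 75th percentile scaling (adjusted p = 0.204). The transglutaminase Tgm2 rose 13.1-fold and the transcription factor Egr2 rose 6.99-fold, both at an adjusted p of 0.00129. The mannose receptor gene Mrc1, at 3.03 ± 0.11 (SD, n = 2) in medium, fell with WGP by 0.64 ± 0.11 on the log2 scale (SE, adjusted p = 0.0148), and its call was lost without medium replicate 2 (adjusted p = 0.0544), WGP replicate 1 (adjusted p = 0.0776) or WGP replicate 2 (adjusted p = 0.0932). Chil3, with 1 of 2 WGP arrays well above background, did not pass the test (-0.46 ± 0.35, SE, adjusted p = 0.348). Of the list's 39 genes with a named probe, 14 had no probe past the filter, as had 9336 of all 20283 named genes. Among them were Arg1, at -5.36 in medium and -5.23 with WGP, and Retnla, at -5.14 and -5.01, which like Ccl17, Ccl22 and Irf4 were not well above background on any array. Ccl17, Ccl22 and Irf4 were singled out after their values were seen.

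Known target genes of NF-kappaB, the transcription factor family of inflammatory signalling, rose nearly throughout. Of 25 measured, 22 rose and 1 fell, with the same counts adjusted over the list alone and a median change of 1.35. The mitochondrial superoxide dismutase Sod2 rose 12.6-fold (adjusted p = 0.00211) and the inhibitor Nfkbie 10.1-fold (adjusted p = 0.0016), and the gene that fell was Nfkbiz. The list's adjusted p was 5.81e-08 in camera, and adjusted p = 0.297 with an estimated correlation. Of 17 chemokine genes, 10 rose and 1, Ccl3, fell (also 10 and 1 adjusted over the list alone). Their median change was 1.54, or 1.13 with genes that were not well above background in one group set at their bound. Cxcl14 was at least 10.6-fold higher (adjusted p = 0.00129) and the neutrophil attractant Cxcl1 at least 2.43-fold (adjusted p = 0.00185). The chemokine list passed camera (adjusted p = 0.00315), with an adjusted p = 0.355 with an estimated correlation. Of 23 cytokines and growth factors, 13 rose and 3 fell (13 and 4 adjusted over the list alone), with a median of 0.72. The interleukin-1 receptor antagonist Il1rn rose 85.0-fold (adjusted p = 0.00186), with 1 of 2 medium arrays well above background, and Il16, Il18 and Ebi3 fell. This list passed camera (adjusted p = 0.044) and had an adjusted p = 0.355 with an estimated correlation. It lost its call in 4 of 19 other settings: median scaling, only probes above background everywhere, every array as its own sample, and without WGP replicate 2 (adjusted p = 0.058, within 0.00972 to 0.262 over all 19).

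Genes that restrain cytokine signalling also rose, in part the same genes as on other lists. Of 22 measured, 16 rose and 1, the phosphatase gene Ptpn22, fell (17 and 2 adjusted over the list alone). Their median change was 1.45, or 1.33 with unmeasured groups at their bound. Of those that rose, Socs2, Socs3, Il10, Il1rn, Tnfaip3, Nfkbia, Bcl3, Dusp1, Dusp4 and Cd274 also stand on other lists. The rise of this list is thus not separate from theirs. The MAP kinase phosphatase Dusp4 rose 8.60-fold (adjusted p = 0.00314). The anti-inflammatory cytokine gene Il10 rose 1.78-fold (adjusted p = 0.00843), a call lost with normexp and quantile normalization (adjusted p = 0.116), without medium replicate 2 (adjusted p = 0.0552) and without WGP replicate 1 (adjusted p = 0.0514). Camera gave this list an adjusted p of 5.08e-05, and adjusted p = 0.297 with an estimated correlation. Of 31 genes of the type I interferon response, 13 rose and 1, Sp100, fell (also 13 and 1 adjusted over the list alone), with a median of 0.20. Ifit1 rose 5.03-fold (adjusted p = 0.00147) and the ubiquitin-like modifier Isg15 rose 3.78-fold (adjusted p = 0.0016). The interferon list passed camera (adjusted p = 0.016), with adjusted p = 0.364 with an estimated correlation. Its call was lost with quantile normalization (adjusted p = 0.0586) and with normexp and 75th percentile scaling (adjusted p = 0.053), within 0.00284 to 0.0586 over 19 settings. Its median lay inside the central 95% of random lists of matched level (-0.17 to 0.34). Of 26 immediate early genes and genes induced through EGR, AP-1 or NFAT, 16 rose and 3 fell (17 and 4 adjusted over the list alone), with a median of 0.86. The small Maf factor Maff was at least 11.9-fold higher (adjusted p = 0.00135), and Klf2, Btg2 and Nr4a1 fell. This list's adjusted p was 0.0101 in camera, and adjusted p = 0.355 with an estimated correlation.

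Beta-glucan receptors and members of the SYK-CARD9 pathway, through which C-type lectin receptors signal, went both ways. Of 28 measured, 13 rose and 6 fell (13 and 8 adjusted over the list alone), and the list did not pass camera (median 0.26, adjusted p = 0.344). The largest changes were the rise of Clec4e and the fall of the transcription factor Nfatc2 (7.83-fold lower, adjusted p = 0.00185). Clec7a, the main beta-glucan receptor, and Il12b had no probe named by the reference table and were not analysed here. Of 19 inflammasome and pyroptosis genes, 9 rose and 5 fell (9 and 7 adjusted over the list alone), with a median of 0.014 and an adjusted p of 0.75 in camera. Mefv, the gene of pyrin, rose 3.78-fold (adjusted p = 0.00289), and Txnip, the thioredoxin-interacting protein, was 4.55-fold lower (adjusted p = 0.00198). P2rx7, Il18, Pycard and Nlrp1a also fell. Of 17 NADPH oxidase and antimicrobial genes, 9 rose and 3, Rac2, Ncf1 and Lyz2, fell (10 and 3 adjusted over the list alone). Among them the acute-phase gene Saa3 rose 10.6-fold (adjusted p = 0.00395), and the list had a median of 0.81. It passed camera (adjusted p = 0.0278, and adjusted p = 0.3855 with an estimated correlation), but not with only probes above background everywhere (adjusted p = 0.0614) or with every array as its own sample (adjusted p = 0.0682), within 0.00619 to 0.0682 over 19 settings. Of 15 genes of MHC class II and costimulation, 6 rose and 3, Cd83, Icosl and H2-DMa, fell (7 and 4 adjusted over the list alone), without passing camera (median 0.25, adjusted p = 0.29). The inhibitory ligand gene Cd274 was at least 7.35-fold higher (adjusted p = 0.002).

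Enzymes and transporters of glycolysis rose, as did genes of the hypoxia response. Of 24 glycolysis genes, 16 rose and 5 fell (17 and 5 adjusted over the list alone), with a median of 0.97. The glucose transporter Slc2a1 rose 8.83-fold and the lactate transporter Slc16a3 6.76-fold, both at an adjusted p of 0.00129, while Slc2a3, Pfkm, Pdk1, Pfkfb4 and Aldoc fell. Camera gave the list an adjusted p of 0.00372, and adjusted p = 0.355 with an estimated correlation. Of 21 hypoxia genes, 15 rose and 4 fell (16 and 4 adjusted over the list alone), with a median of 0.98. Bhlhe40, a transcriptional repressor, rose 12.3-fold (adjusted p = 0.00136) with 1 of 2 medium arrays well above background, and Ndrg1, Pdk1, Car9 and Loxl2 fell. Another kept probe of Loxl2 had the opposite sign. The hypoxia list's adjusted p was 0.00315 in camera, and adjusted p = 0.355 with an estimated correlation. Of 30 genes of oxidative phosphorylation, 8 rose and 1, Sdhc, fell, with another kept probe of Sdhc of opposite sign (6 and 1 adjusted over the list alone). Their median was 0.32, with Cycs, cytochrome c, 2.45-fold higher (adjusted p = 0.00363) and Ndufa4 1.70-fold higher (adjusted p = 0.00771). The call of Ndufa4 was lost without medium replicate 2 (adjusted p = 0.0516) and without WGP replicate 2 (adjusted p = 0.0655). The list passed camera (adjusted p = 0.0256), with adjusted p = 0.355 with an estimated correlation. Its call was lost with quantile normalization, in both normexp settings and without WGP replicate 2 (adjusted p = 0.0736), within 0.00977 to 0.428 over 19 settings. Its median lay inside the central 95% of matched random lists (-0.075 to 0.39). Of 28 genes of the citric acid cycle and fatty acid oxidation, 3 rose (Pcx, Idh3a and Mdh2) and 10 fell (3 and 11 adjusted over the list alone), without passing camera (median -0.19, adjusted p = 0.197). Pyruvate carboxylase, Pcx, rose 3.08-fold (adjusted p = 0.00225) and the thiolase Acaa2 was 2.64-fold lower (adjusted p = 0.00273).

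Genes of cholesterol synthesis rose with no fall among them. Of 21 measured, 16 rose and 0 fell (17 and 1 adjusted over the list alone or at an unadjusted p under 0.05 in limma), with a median change of 1.62. Squalene epoxidase, Sqle, rose 9.17-fold (adjusted p = 0.00129). Camera gave the list an adjusted p of 2.52e-05, and adjusted p = 0.297 with an estimated correlation. Of 23 genes of LXR and lipid handling, 11 rose and 3, Mertk, Lpl and Abcg1, fell (12 and 3 adjusted over the list alone), with a median of 0.43. The fatty acid binding protein Fabp4 rose 8.47-fold (adjusted p = 0.00139), and Mertk, a receptor for the uptake of dying cells, was 3.70-fold lower (adjusted p = 0.00177). The lipid list passed camera (adjusted p = 0.0278), with adjusted p = 0.4455 with an estimated correlation. It lost its call in 5 of 19 settings, namely quantile normalization, median scaling, both normexp settings and without WGP replicate 2 (adjusted p = 0.0736), within 0.00767 to 0.165 over all 19. Of 33 lysosome and phagosome genes, 13 rose and 3, Atp6v0a1, Lgmn and Hexa, fell (14 and 3 adjusted over the list alone), with a median of 0.23. Cathepsin L, Ctsl, rose 4.87-fold (adjusted p = 0.0015). Atp6v1h, a subunit of the proton pump, rose 3.69-fold (adjusted p = 0.0113), a call lost without WGP replicate 2 (adjusted p = 0.0613). The lysosome list passed camera (adjusted p = 0.0278, and adjusted p = 0.374 with an estimated correlation), and lost its call with quantile normalization, in both normexp settings and without WGP replicate 2 (adjusted p = 0.0943), within 0.0101 to 0.338 over 19 settings. Its median, too, lay inside the central 95% of matched random lists (-0.079 to 0.37).

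Genes of the oxidative stress response under the transcription factor NRF2 rose, among them enzymes of glutathione and thioredoxin metabolism. Of 28 measured, 21 rose and 1, Sesn2, fell (22 and 2 adjusted over the list alone), with a median of 1.13. Besides Gsta3, the largest change was that of sulfiredoxin, Srxn1, which rose 19.0-fold (adjusted p = 0.00129). The list's adjusted p was 1.9e-06 in camera, and adjusted p = 0.297 with an estimated correlation. Of 22 genes of the unfolded protein and integrated stress responses, 10 rose and 1, Herpud1, fell (13 and 1 adjusted over the list alone), with a median of 0.58. The transcription factors Cebpb and Atf4 rose 6.35-fold (adjusted p = 0.00136) and 3.29-fold (adjusted p = 0.00666). This list passed camera (adjusted p = 0.00112), and had an adjusted p = 0.3295 with an estimated correlation.

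Extracellular proteases, their inhibitors and matrix receptors formed the list with the largest median change, 2.05, or 1.99 with unmeasured groups at their bound. Of 23 measured, 19 rose and 0 fell (20 and 0 adjusted over the list alone or at an unadjusted p under 0.05 in limma). The membrane-bound metalloproteinase Mmp14 rose 42.6-fold (adjusted p = 0.00129), with 1 of 2 medium arrays well above background, and the collagenase Mmp13 was at least 2.00-fold higher (adjusted p = 0.00178). Camera gave an adjusted p of 9.68e-07, and adjusted p = 0.297 with an estimated correlation. Of 11 osteoclast markers, 6 rose and 1, Nfatc1, fell (7 and 1 adjusted over the list alone), with a median of 1.09. The fusion protein gene Dcstamp rose 8.31-fold and the integrin Itgb3 5.29-fold, both at an adjusted p of 0.00129. The osteoclast list passed camera (adjusted p = 0.0461, and adjusted p = 0.364 with an estimated correlation). It lost its call in 9 of 19 settings, among them the slide block (adjusted p = 0.0562), without medium replicate 1 (adjusted p = 0.0513) and without WGP replicate 1 (adjusted p = 0.075), within 0.012 to 0.0766 over all 19. Of 18 cell cycle genes, 7 rose and 2, Tyms and E2f1, fell (the same counts adjusted over the list alone), without passing camera (median 0.34, adjusted p = 0.29). The proliferation marker Mki67 rose 4.0-fold (adjusted p = 0.00156) and the replication clamp Pcna 2.44-fold (adjusted p = 0.0032).

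**Figure D3:**
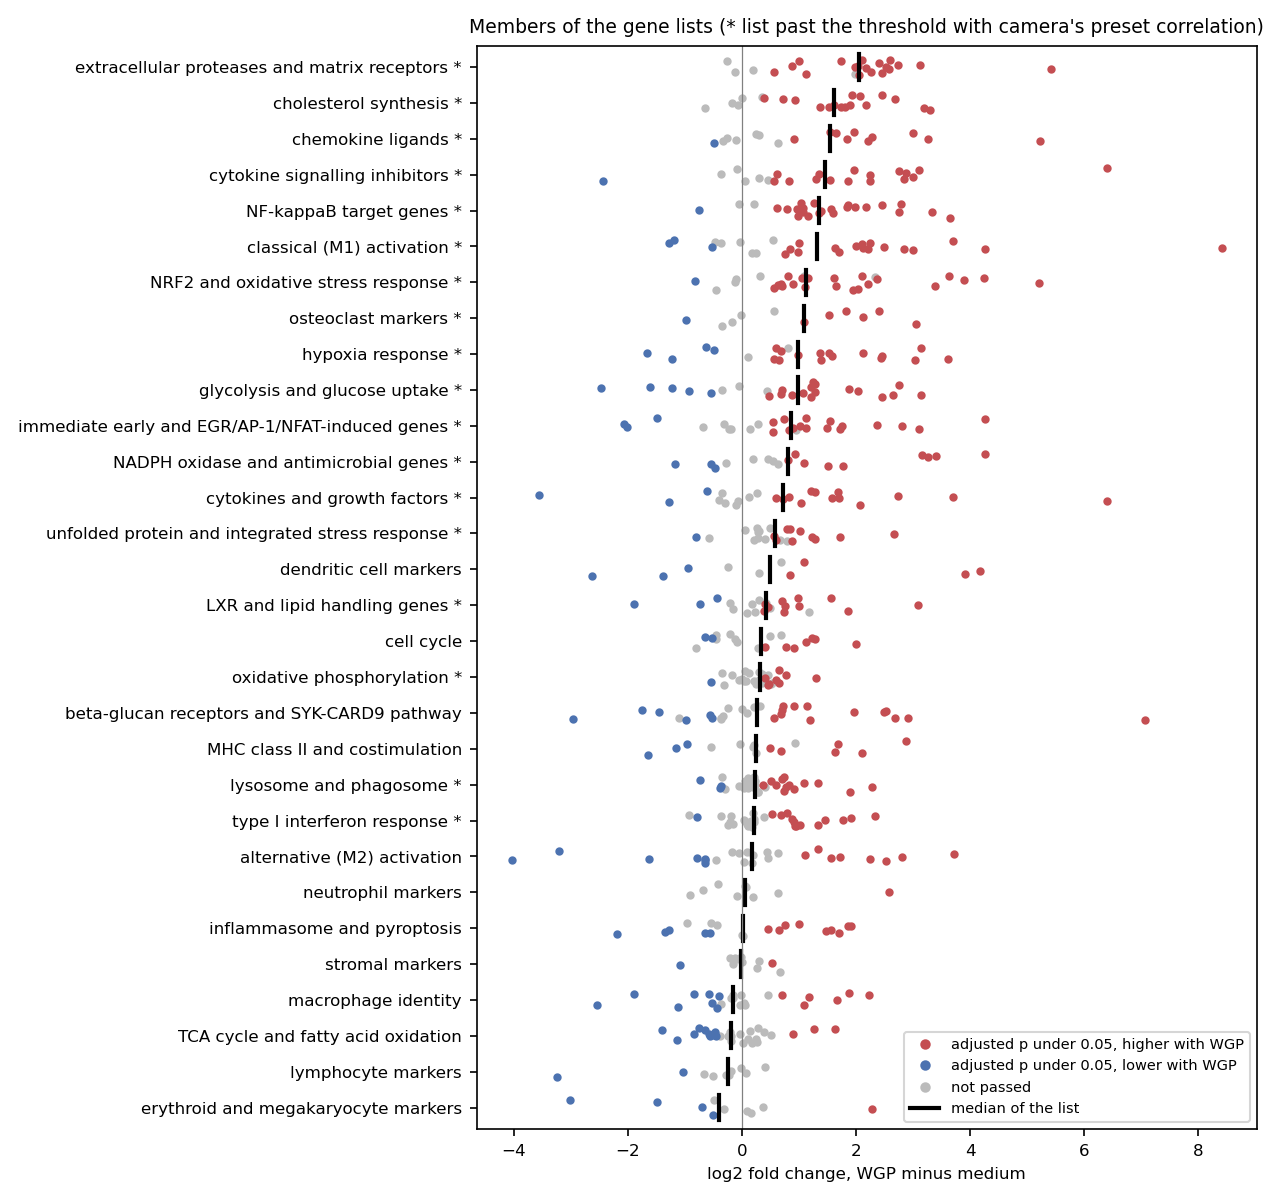
Change with WGP of each measured member (points, x axis, log2 units, WGP minus medium, 2 independent arrays per group) of the 30 gene lists tested (y axis), ordered by the list's median (black bar). Red and blue points passed the test in limma, grey points did not, and an asterisk marks the 18 lists past the threshold in camera with its preset correlation, none of which passed with an estimated correlation. Extracellular proteases and matrix receptors have the highest median, 2.05.

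Of the 30 lists tested, 18 passed camera with its preset correlation of 0.01, and 11 of these passed in all 19 other settings of scaling, filter, fit and left-out arrays. Among the 19, leaving out replicate 3 and using only the first of the alike arrays are the same fit and drop only a copy. The authors' values are nearly those of the main fit, so these settings could hardly differ from it. All 18 had medians of the same sign on both slides, and 17 lists passed with the slide as a block. With the correlation estimated from the residuals of 4 arrays, 0 lists passed in limma, 5 had an unadjusted p under 0.05, and the adjusted p of the 18 lists lay between 0.297 and 0.4455. Against random lists of matched level, 15 of the 18 had a median outside the central 95%, and 3 (type I interferon, oxidative phosphorylation and lysosome) inside it. Of the lists that did not pass camera, 4 (citric acid cycle and fatty acid oxidation, cell cycle, macrophage identity and dendritic cells) had a median outside it. Members named because 5 or fewer of their list went one way were picked after their values were seen.

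Macrophage identity genes had a median level of 4.76 in medium and 4.84 with WGP. Of 23 measured, 6 rose and 8 fell (7 and 8 adjusted over the list alone), without passing camera (median -0.15, adjusted p = 0.344). The transcription factor Maf was 5.84-fold lower (adjusted p = 0.00129). Of 10 dendritic cell markers, 4 rose (Cd24a, Id2, Siglech and Ccr7) and 3 fell (Batf3, Tcf4 and Ccr9), the same counts adjusted over the list alone, with an adjusted p of 0.761 in camera. Cd24a rose 18.1-fold and Id2 15.1-fold, both at an adjusted p of 0.00129. Of 9 neutrophil markers, 1 rose (0 adjusted over the list alone, 2 at an unadjusted p under 0.05 in limma), the collagenase Mmp8, which is also on the protease list (5.94-fold, adjusted p = 0.0211, 1 of 2 medium arrays well above background). Its call was lost without WGP replicate 1 (adjusted p = 0.0686) or WGP replicate 2 (adjusted p = 0.0866), and the neutrophil list had an adjusted p of 0.936 in camera. Of 10 erythroid and megakaryocyte markers, 1 rose and 4 fell (also adjusted over the list alone), with an adjusted p of 0.29 in camera. The platelet chemokine gene Pf4, which is also on the chemokine list, rose 4.86-fold (adjusted p = 0.00341), and Epor, Gp1bb, Hba-a1 and Treml1 fell. Epor was at least 6.87-fold lower (adjusted p = 0.0131), which was lost without medium replicate 1 (adjusted p = 0.0622) or medium replicate 2 (adjusted p = 0.079).

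Of 10 lymphocyte markers, 0 rose and 2 fell (also adjusted over the list alone, or at an unadjusted p under 0.05 in limma), both of them parts of the B-cell receptor, with an adjusted p of 0.111 for the list in camera and 0.0306 with no filter on dim probes. Cd79b was at least 5.04-fold lower (adjusted p = 0.00916), which was lost without medium replicate 2 (adjusted p = 0.0689). Cd79a was 2.05-fold lower (adjusted p = 0.0246) with 1 of 2 WGP arrays well above background, which was lost in both normexp settings, without WGP replicate 1 (adjusted p = 0.0853) and without WGP replicate 2 (adjusted p = 0.103). Of 11 stromal markers, 1 rose and 1 fell (0 and 1 adjusted over the list alone), with an adjusted p of 0.936 in camera. Col6a1 rose 1.44-fold (adjusted p = 0.0402), and lost its call with the slide block (adjusted p = 0.0651), in both normexp settings and without medium replicate 1 (adjusted p = 0.126), medium replicate 2 (adjusted p = 0.112), WGP replicate 1 (adjusted p = 0.172) or WGP replicate 2 (adjusted p = 0.0901). Col3a1 was at least 1.62-fold lower (adjusted p = 0.00534). With normexp and 75th percentile scaling, though, its change was 0.093 on the log2 scale, and so reversed. Its call was lost with normexp and quantile normalization (adjusted p = 0.8325). The offset of normexp shrinks changes at such low levels by construction, so these settings do not decide its direction. Of the markers of mast cells, basophils and eosinophils, 3 were measured, too few for the list test, and 0 passed the test in limma at an adjusted p under 0.05, with 0 at an unadjusted p under 0.05.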

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

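Among the tests in this part, those of medium replicate 3 averaged with replicate 1 (5248 genes changed) and of other probes' signs were chosen after the data were seen. With median scaling, 1199 genes were lower with WGP. Changes of at least 2-fold numbered 561 after normexp with quantile normalization and 559 with 75th percentile scaling. Normexp added an offset of 50, where the 75th percentile of the processed signal was 56.1 to 85.8 on the independent arrays. This shrinks the changes of dim genes by construction. With no filter on dim probes, 1532 of 20274 genes changed, 895 higher and 637 lower. Each kept probe by itself gave 2871 lower and 2545 changes of at least 2-fold among 18442 probes. Counting every array as its own sample gave 7449 changed genes, 4113 higher and 3336 lower, as copies of an array shrink the spread. At a threshold of 0.01, 1777 genes changed. Leaving out 1 replicate gave 1715 to 4439 changed genes, 964 to 2537 higher and 751 to 1902 lower. The upper ends, 4439, 2537 and 1902, come from leaving out replicate 3, which drops only a copy of an array. Leaving out any of the independent arrays gave fewer changed genes, with 1 array left in its group. Camera with an estimated correlation passed 0 lists, and fry 24, where fry does not compare a list with other genes. Against matched random lists, 19 medians lay outside the central 95%. With the replicate block, which is also the slide, 4090 genes changed, and among the named genes and lists it ended the calls of Col6a1 and the osteoclast list and no other. The change of Col3a1 reversed to 0.093 with normexp and 75th percentile scaling. Its level was only -2.64 in medium and -3.73 with WGP, where the offset outweighs the signal, so this setting does not decide its direction. For these, except where the construction is named, the cause was not tested. Of 4441 changed genes, 3836 were also called after quantile normalization and 3731 after median scaling, with 0 of opposite sign. The 79 named genes that changed kept their direction and call in 1065 of 1084 settings without left-out arrays, lost the call in 18 and reversed in 1. With a left-out array they kept it in 371 of 395 and lost it in 24. The 395 include leaving out replicate 3, which drops only a copy. The 1084 include that same fit, as using only the first of the alike arrays. Without both arrays of a replicate no test was possible. Dim probes limit the rest, as 45.0% to 50.6% of probes were well above background.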

Other observations

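In this part, the tests of spiked-in controls, of dimmer arrays, of lists without a probe past the filter and of replicate 3 were chosen after the result was seen. Some genes of one family or one list changed in opposite directions with WGP (picked after their values were seen). Of the glucose transporters, Slc2a1 rose by 3.14 ± 0.11 on the log2 scale (SE, adjusted p = 0.00129) and Slc2a6 rose 5.50-fold, while Slc2a3 fell to a level not well above background, at least 2.92-fold lower. Of the Maf factors, the large factor Maf fell by 2.55 ± 0.091 (SE), and the small factor Maff was at least 11.9-fold higher. Within the beta-glucan receptor and SYK-CARD9 list, the receptors Clec4e, Clec4d, Clec4n and Tlr2 rose by 7.065, 2.52, 1.97 and 2.49 on the log2 scale. The adaptor Card9 fell by 0.54, the kinase Lyn by 1.46 and the factors Nfatc1 and Nfatc2 by 0.99 and 2.97. Within the dendritic cell list, Id2 rose by 3.92 and Batf3 fell by 2.62. All of these passed limma's test at an adjusted p under 0.05, and no test of the difference between such genes was run.

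In all, 40.57% of the tested genes changed between 2 and 2 arrays. The arrays can be split into 2 and 2 in 3 ways, too few for a share under 0.05, and 1 of the 3, the real one, gave as many as 4441 genes in limma, while the other splits gave 0 each (91 and 15 genes at an unadjusted p under 0.05). A difference in labelling, hybridization or position on the slide could give such changes. The spiked-in control RNAs should be equal on all arrays. For signals well above background, they argue against an effect across the whole array as the main source. The WGP minus medium differences of the 7 controls well above background had an SD of 0.12 and a range of -0.17 to 0.15, 0.139 times the SD of the genes (upper 95% bound 0.306). Each control was averaged over 32 spots, more than any gene's probe, which hides effects local to single spots. The controls left out as dim differed by -0.60, 0.26 and -0.012. Dimmer WGP arrays are not decided. After quantile normalization 86.38% of the changed genes were also called, so most calls did not depend on this choice of scaling. Both scalings start from the same background-subtracted signal, so an effect of brightness on that signal could remain in both. With median scaling the share of higher genes among those changed went from 57.17% to 72.69%. A biological effect of WGP, which the design names, stays open as a hypothesis with no test beyond this comparison, and chance is not decided by so few splits.

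A second pattern is the low signal of several genes known as markers of alternative activation in cells labelled M2. In the alternative activation list, 14 of 39 genes had no probe past the filter, against 1 of 24 in the macrophage identity list (Fisher's exact test, p = 0.00507). This test decides nothing about probes that miss their transcripts, since the identity list was chosen as expressed in macrophages. The share was much the same in the classical activation list, 13 of 39. It was 16 of 39 for cytokines and growth factors, 12 of 29 for chemokines and 9336 of 20283 for all named genes. None of these was chosen as expressed in cells labelled M2. Like shares therefore do not decide whether the low signal is particular to markers of alternative activation. Failed probes and transcripts that were not expressed both stay open. The labels name no polarizing agent and there is no unpolarized group, so no biological explanation was tested.

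The last pattern is replicate 3. Were these files hybridizations of their own, their processed signals should differ from those of the other replicates by more than rounding. The largest departure from the mean of replicates 1 and 2 was 0.695% in medium, and the largest departure from 1.3 times replicate 1 was 0.498% with WGP. The header of medium replicate 3 nevertheless named a slide of its own, slide 3. How the files came to hold these values stays open. No biological explanation was tested. Counting all 6 files as samples raised the number of changed genes from 4441 to 7449.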
